A study of Mus musculus with 3 samples.

How the data were processed

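H3K27me3 chromatin immunoprecipitation was done on gastrocnemius muscle of young mice, with 1 WT library, 1 NADS KO library and 1 pooled input. Per the labels' protocols, tissue was fixed in 1% formaldehyde, chromatin was sheared to 300 to 500 bp, and 30 µg of chromatin was taken with 4 µl of antibody and 35 µl of Drosophila chromatin. The submitters' processing notes name the builds GRCm38 and mm10. The aligner and peak caller are not given in the sources used here.

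The table analysed is the authors' report of the MEIRLOP tool, which fits, per motif, a logistic regression of motif presence in a peak on the peak's score and on any covariates. The title line says that scores came from the authors' edgeR comparison of WT with KO with spike-in, per the file headers. Tool versions, covariates, the motif matrices, the cutoff for a motif match, and the unit and sign of the score are not given in the sources used here. Coefficients, standard errors and interval bounds are on a natural log scale, per the file headers and the values. The area under the receiver operating curve is a fraction from 0 to 1, per the file headers. Each p-value and adjusted p-value is the authors', rounded to 6 decimals, so that 1842 adjusted values are listed at 0. The share of peaks with a motif is in percent, deposited beside the number of peaks. The sum of 75161 scored peaks follows from these 2 columns.

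The planned comparisons of peak levels, genes, chromosomes and hyaluronan synthase genes between WT and KO were not run, because the table holds motif regressions and not values per peak or library. The planned pseudocounts, filters, centring and overlaps were not run for the same reason. Motifs were used in place of peaks, which was chosen after the table was seen. No count model was fitted here and no p-value was computed between genotypes. Depth per library was not analysed here, so its effect on precision is unknown. Intervals, p-values and adjusted values were checked against a Wald test and Benjamini-Hochberg adjustment over 1949 motifs and differed by at most 3.12e-06.

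Named motifs follow the rule fixed before the data were examined for a table without values per library: the 10 highest and 10 lowest, here by coefficient, and the highest and lowest member of each gene list with at least 3 members. Some motifs that this rule names are not reported here. Other names were chosen after their values were seen. A motif was called mouse-named when each factor in its name matched a symbol of GRCm38.p6 genes, ignoring case, or for 30 motifs an older symbol. This gave 780 motifs, 704 of single factors and 76 of pairs, after 54 motifs whose name or matrix number belongs to other organisms were left out from general knowledge of the matrix numbers. The older symbols and the exclusions by matrix number, including that of an insect CTCF matrix, were added after coefficients had been seen. The first mapping, without them, gave 774 motifs, and both are compared in the closing section. For gene lists each gene counted once, by its motif in most peaks, giving 651 genes with a median of 0.190. A list's percentile is over 10000 random lists of the same size, matched in 10 bins of the percent of peaks, and describes these libraries only. On simulated values for these 651 genes, with 40 lists of 30 genes per shift, the median passed the 97.5 percentile in 2.5% of lists without a shift, 70% with a shift of 0.02 and 100% with 0.05. With lists of 13 it did so in 0%, 25% and 100%, with lists of 4 in 5%, 12.5% and 42.5%, and with lists of 3 in 0%, 15% and 40%, so a shift of 0.05 was missed in most lists of 3 or 4. Each rate rests on 40 lists and need not hold for lists of related factors with like motifs.

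Alternatives, all chosen after the data were seen, were a minimum of 1000 peaks, the upper 50% by number of peaks, 1 row per name, mouse-named motifs under 3 name mappings, Bonferroni adjustment, doubled standard errors, inverse-variance weights, the mean over a gene's motifs, a pool of all motifs, a myogenic list without HES1 and HEY1, and the ratio of coefficient to standard error. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.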

Results

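H3K27me3, the histone mark laid down by Polycomb repressive complex 2, was profiled by chromatin immunoprecipitation and sequencing in gastrocnemius muscle of young mice. There was 1 wild-type (WT) library, 1 library from NADS knockout (KO) mice and 1 pooled input, with Drosophila chromatin added to the immunoprecipitations as a spike-in. The series title ties early-life NAD⁺ deficiency to hyaluronic acid synthesis in aging muscle. The values analysed here are a table of 1949 transcription factor motifs, each tested for whether its presence in a peak went with the peak's score in the authors' comparison of WT with KO, over 75161 scored peaks. Which genotype a higher score favours is not given in the sources used here, so no direction between WT and KO is drawn. Peak positions, genes near peaks, levels per library and sequencing depth were not analysed here. With 1 library per genotype there is no replicate check, and each interval below covers variation between peaks of these 2 libraries, not between animals.

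The first question was which motifs went with a higher or lower score. The coefficient is the change, per unit of score, in the natural log of the odds that a peak holds the motif. In the authors' deposited table it was positive for all 1949 motifs and negative for 0. MEIRLOP's adjusted p-value was under 0.05 for 1934 of them in the authors' deposited table, the same number as at an unadjusted p under 0.05. The median coefficient was 0.194, an odds ratio of 1.21 per unit of score, with quartiles of 0.164 and 0.227. The 15 motifs not past the threshold lay in 94 to 971 peaks each, and 12 of them were named for mouse genes. Because nearly all motifs passed, motifs are described below by whether their 95% interval lay above or below the median of all motifs. It lay above for 556 (28.5%), below for 535 (27.4%) and spanned it for 858. All rows describe the same peaks, and motifs of related factors resemble each other, so motifs are not independent.

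**Figure D1:**
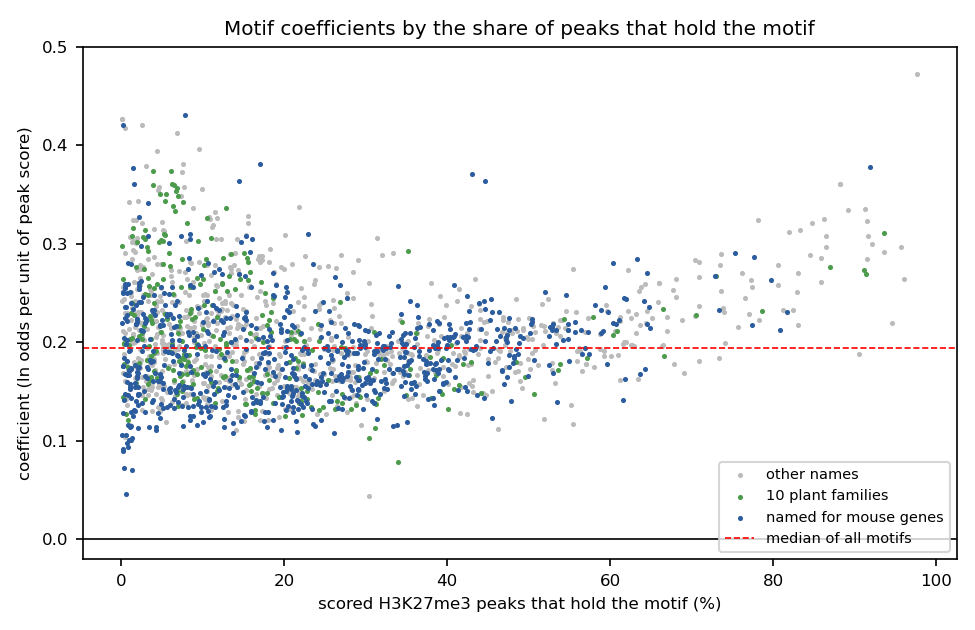
Coefficient of each of the 1949 motifs (change in the natural log of the odds per unit of peak score) against the percent of scored H3K27me3 peaks that hold the motif, coloured by the kind of name. The dashed line is the median of all motifs. All points lie above 0, from 0.0445 to 0.473.

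Of the 10 highest coefficients, 2 belonged to mouse-named motifs. Nrf1, a regulator of nuclear genes for mitochondrial function, had 0.430 (95% interval 0.398 to 0.463) and was found in 7.82% of peaks in the authors' deposited table. The cell cycle factor E2F7 had 0.421 (0.262 to 0.581), but from 144 peaks, in the authors' deposited table. The other 8 of the 10 highest were not counted as mouse-named: RGM1 0.473, E2FD and E2FE 0.427 each, FAR1 0.421, PDR3 0.418, Os05g0497200 0.413, FHY3 0.396 and CAMTA1 0.394 in the authors' deposited table. RGM1, a yeast factor, lay in 97.7% of peaks in the authors' deposited table, and E2FD and E2FE had identical rows from 106 peaks. Among further mouse-named motifs, chosen after their values were seen, the authors' deposited table gave TCFL5 0.381, ZNF354C 0.378, E2F4 0.377 and ZBTB14 0.364. Pairs with Arnt, the partner of the dioxin receptor and of hypoxia-inducible factors, also stood high in the authors' deposited table, Ahr::Arnt at 0.371 and ARNT::HIF1A at 0.364.

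The lowest coefficients were mostly of mouse-named factors, 8 of 10, and most came from few peaks. The insulator factor CTCF had 0.0464 (95% interval -0.0650 to 0.158, adjusted p 0.414) and 0.0709 (-0.00421 to 0.146, adjusted p 0.0646) in 2 rows of the authors' deposited table. Those rows lay in 442 and 971 peaks, while a further CTCF row in 5610 peaks had 0.136 and its paralog CTCFL had 0.245 in the authors' deposited table. The glucocorticoid receptor NR3C1 had 0.0937 (adjusted p 0.0543) and the thyroid hormone receptor THRB 0.101 (adjusted p 0.0146) in the authors' deposited table. ZNF8 at 0.0725, IRF4 at 0.0898 and RARA at 0.0913 did not pass the threshold in the authors' deposited table. The lowest of all, RDS1 at 0.0445, and ERF069 at 0.0789 were not mouse-named and lay in 22829 and 25516 peaks in the authors' deposited table.

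Motifs were then grouped by factor family, with families chosen after the table was seen but before their values were computed. All motifs of all 35 families had positive coefficients; 13 family medians lay above the median of all motifs and 22 below. The E2F family of cell cycle factors had the highest median, 0.341, with 6 of 7 intervals above the median of all motifs and none below, although its median ratio of coefficient to standard error minus that of all motifs was -1.03. The EGR family, zinc fingers of the early growth response, had 0.296 with 4 of 4 above, and the KLF and SP zinc fingers 0.241 with 19 of 23 above. The MEF2 family, regulators of muscle genes, had 0.224 with 1 of 4 above and 3 spanning, and by the ratio to the standard error it too lay below all motifs, at -2.29. At the other end, AP-1, the stress-responsive Fos and Jun dimers, had a median of 0.134 with 32 of 37 intervals below. SOX factors had 0.140 with 16 of 18 below, STAT factors, which relay cytokine signals, 0.153 with 7 of 7 below, and TEAD factors, which act in Hippo signalling, 0.155 with 4 of 4 below. GATA factors had 0.162 with 6 of 6 below, but their median ratio to the standard error lay above that of all motifs by 0.196. CTCF and CTCFL had a median of 0.103 over 4 rows, 2 of them in under 1000 peaks. The intervals of all 3 CTCF rows lay below the median of all motifs and that of CTCFL above. Among motifs in at least 1000 peaks 2 rows were left, CTCF at 0.136 (0.103 to 0.168) and CTCFL at 0.245. Pooled, these 2 lay -0.00357 from the median of those motifs. They lay on the other side, at 0.0270, with an insect CTCF row that was left out only after its value was seen.

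**Figure D2:**
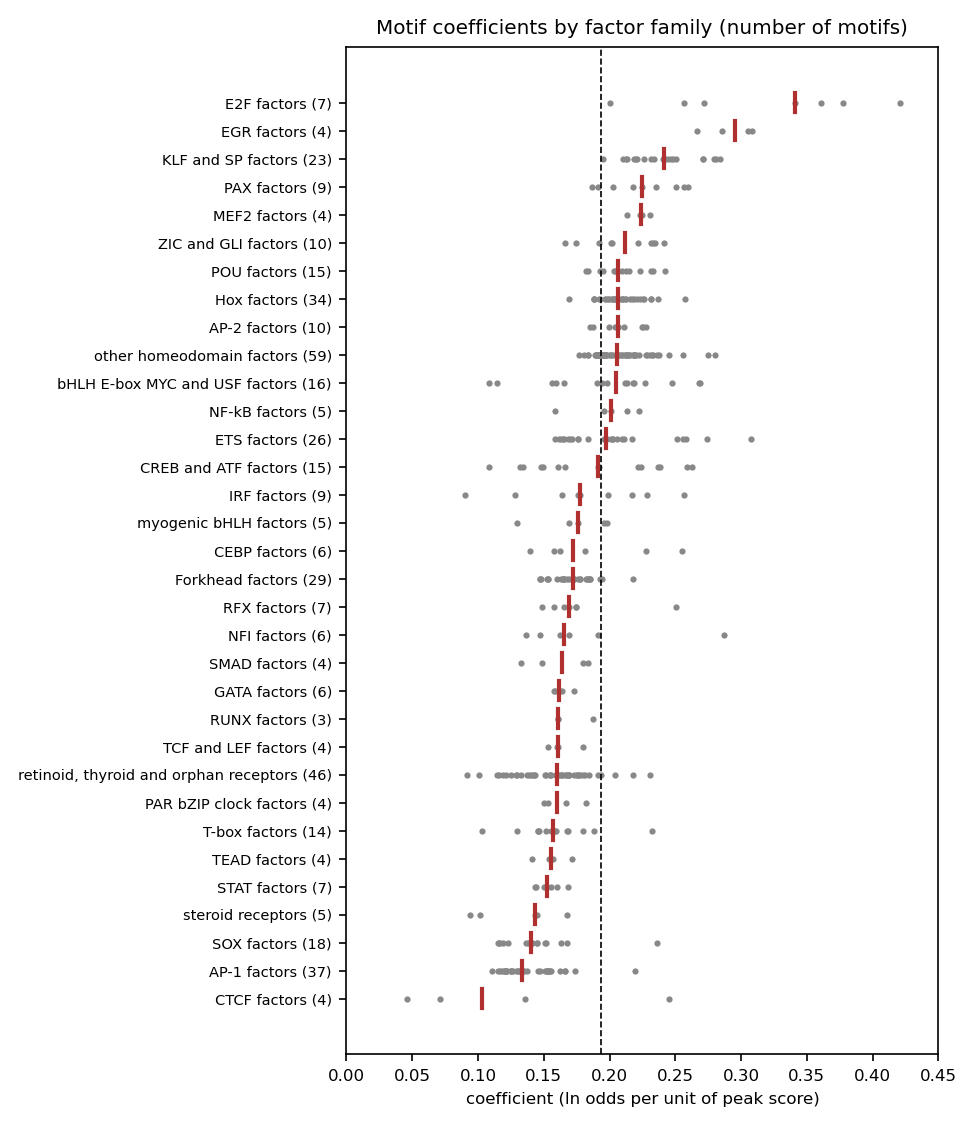
Coefficients (natural log of the odds per unit of peak score) of the motifs of factor families (2 of the 35 families are not drawn), one point per motif with the number of motifs in brackets; red bars are family medians and the dashed line is the median of all motifs. Family medians run from 0.103 for CTCF factors to 0.341 for E2F factors.

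The 20 gene lists fixed before the data were examined could be used only where their members name a motif. No member of the hyaluronan synthesis, hyaluronan turnover, NAD, Polycomb, contractile or collagen list did, so these 6 lists have no value. A further 8 lists had 1 or 2 members and were not described, and 6 had at least 3. For those 6, the median was set against 10000 random lists from 651 mouse genes, matched on the percent of peaks. Random lists drew genes singly, while these lists hold groups of related factors with like motifs, so the random ranges may be too narrow. No allowance was made for comparing 6 lists.

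Myogenic and satellite cell factors had a median of 0.213 over 13 motifs, at percentile 98.2 of the random lists (95% of them between 0.158 and 0.211). All 13 were past the threshold; 5 intervals lay above the median of all motifs, 3 below and 5 spanned it. The Notch effectors HES1 (0.310) and HEY1 (0.302), the satellite cell factors PAX3 (0.257) and Pax7 (0.235), and MEF2A (0.231) were above in the authors' deposited table. A further PAX3 row in 1492 peaks, not used for the list, had 0.203 (0.143 to 0.262) and spanned the median in the authors' deposited table. MYF6 (0.130) and Six4 (0.143) were among those below in the authors' deposited table. The intervals of the muscle-determining factors MYOD1 (0.198), MYOG (0.196) and MYF5 (0.176) spanned the median, as those of MEF2C (0.213) and MEF2D (0.224) did, in the authors' deposited table. Without HES1 and HEY1 the list lay at percentile 88.9, and in the upper 50% of genes by number of peaks its 5 members lay below the pool median, at -0.0163.

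**Figure D3:**
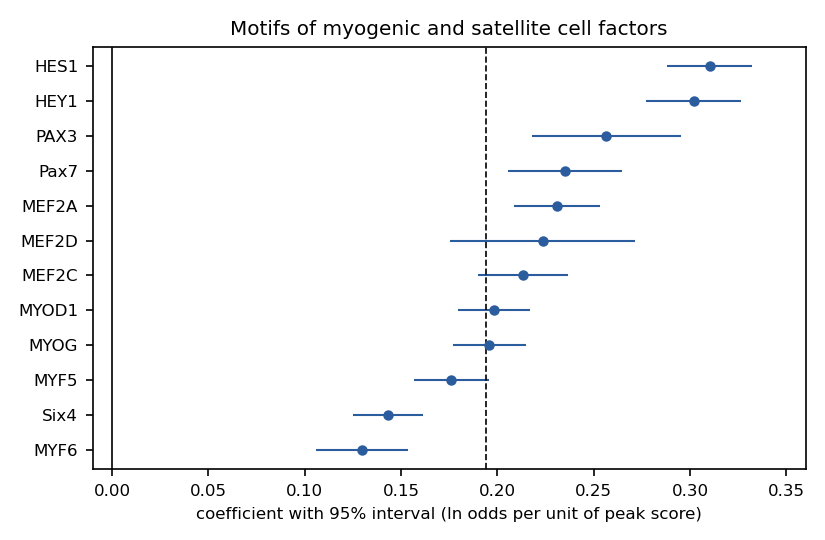
Coefficients of motifs of myogenic and satellite cell factors (change in the natural log of the odds per unit of peak score) with the authors' 95% intervals. Of the 13 motifs, 1 is not drawn, and the dashed line is the median of all motifs. HES1 and HEY1 lie highest, at 0.310 and 0.302, and MYF6 lowest, at 0.130.

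Hox factors, which set position along the body axis, had a median of 0.207 over 34 motifs, at percentile 84.1. Of these, 9 intervals lay above the median of all motifs and 1 below, from Hoxd13 at 0.169 to HOXC11 at 0.257 in the authors' deposited table. Other developmental factors had a median of 0.191 over 103 motifs, at percentile 35.9, with 20 above and 32 below. Their extremes in the authors' deposited table were PAX2 at 0.259, from 604 peaks, and TBXT at 0.103, from 944 peaks. Lists of other cell types in muscle lay inside their random ranges, but with 3 or 4 motifs each a shift in them could easily be missed. Fibro-adipogenic progenitor and fibroblast factors were at percentile 27.2 (4 motifs, median 0.183), leukocyte factors at 17.7 (4 motifs, 0.182) and endothelial and mural factors at 9.84 (3 motifs, 0.166). Their extremes in the authors' deposited table were Hic1 0.244 and TCF7L2 0.161, PAX5 0.218 and Spi1 0.169, and PROX1 0.222 and SOX18 0.163. All members of these 5 lists were past the adjusted threshold.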

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

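All alternatives here were chosen after the data were seen; the planned ones, on values per peak, were not run. No paired analysis was possible because each genotype has 1 library. Of all motifs, 99.2% had a 95% interval above 0, and 96.3% with standard errors doubled. The percent past the adjusted threshold was 95.9 by Bonferroni, 96.2 with standard errors doubled, 98.5 for mouse-named motifs with or without the insect CTCF matrix, and 100 in at least 1000 peaks or in the upper 50% by number of peaks. The median was 0.191 in that upper 50%, and 0.185 for mouse-named motifs, 0.185 with the insect CTCF matrix and 0.187 by the first name mapping. Of 19 list comparisons 17 kept their direction. Against a pool of all motifs, with a median of 0.194 in place of 0.190, developmental factors turned from 0.00105 to -0.00291. In the upper 50% by number of peaks myogenic factors turned to -0.0163, with 5 genes left. HES1, HEY1, MEF2A, PAX3 and Pax7, whose intervals lay above the median of all motifs, were in fewer peaks and not among those left. In at least 1000 peaks 34 of 35 families kept their side of the median, and IRF turned to 0.00315, with 4 motifs left. CTCF turned to 0.0270 there if the insect matrix, left out only after its value was seen, was kept. By the ratio of coefficient to standard error, which also depends on the number of peaks, 25 of 35 families kept their side. It turned to -1.03 for E2F, -4.99 for PAX, -2.29 for MEF2 and -2.99 for ZIC and GLI, and to 1.75 for myogenic bHLH, 1.28 for forkhead, 0.196 for GATA, 1.32 for RUNX, 0.185 for TCF and LEF and 0.251 for T-box factors. Depth per library was not analysed here.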

Other observations

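PAX factors of early development had a median of 0.225 with 3 of 9 intervals above the median of all motifs and none below, and homeodomain factors outside the Hox clusters 0.206 with 19 of 59 above and none below; by the ratio to the standard error PAX factors lay below all motifs, at -4.99. Forkhead factors had 0.172 with 16 of 29 below, although that ratio put them 1.28 above all motifs. ETS factors had 0.197 and were split, with 6 above and 8 below of 26. Motifs named for 10 plant families had a median of 0.195 over 300 motifs, with ERF factors at 0.290 and WRKY factors at 0.151.

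Of the tests below, those of peak width, of base composition for the common sign, of GC content without CpG, and of the lowest motifs split by number of peaks were chosen only after the results were seen. No biological difference between WT and KO was tested.

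Base composition alone was assumed to give AT-rich and GC-rich families opposite signs. The lowest coefficient of the AT-rich families was 0.147 and that of the GC-rich families 0.166, both with intervals above 0. Every coefficient was already known to be positive, so this restates that result and is no separate test. The signs differ from what was assumed for base composition alone, but the covariates of the fit are not given, so a part played by it stays open. RDS1 had the lowest coefficient, 0.0445, yet an area under the receiver operating curve of 0.818. So weak a score term would hardly give that area alone, so the fit may hold other terms. Coefficients here and below may thus be adjusted for properties of the peaks that are not named. Binding by mouse factors would give mouse-named motifs a higher median than plant motifs. The mouse-named median instead differed from the plant median by -0.00990, which met the bound set beforehand against this explanation, 0 or less. By that rule the values would go against it for mouse-named motifs as a set. The plant median depends on the families chosen, however, which ran from 0.151 for WRKY to 0.290 for ERF factors. The intervals of both medians also overlapped, at 0.180 to 0.190 and 0.185 to 0.203, so binding by mouse factors is not called excluded and stays open. Wider peaks at higher scores may hold more of any motif: the median coefficient of motifs in over 80% of peaks was 1.46 times that of motifs in under 20%, and 1.28 times among mouse-named motifs, which make up 3 of the 37 in over 80%. Both are below the 2.25 that the formula behind this test gives and the bound of 1.5 set for it, and motifs in 20 to 40% of peaks went the other way, at 0.898. Width was not analysed here and the formula is an assumption, so it stays open.

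The lowest 10% of coefficients, 195 motifs, may be low only because few peaks hold them. Of all 195, 11.8% had an interval that reached the median of all motifs, between the bounds set beforehand, so the whole set was not decided. Split by number of peaks, 2.94% of 170 motifs in at least 1000 peaks reached it, which argues against imprecision there, while 72.0% of 25 motifs in fewer peaks did. The latter decides nothing, since even the narrowest of those intervals extends 0.0751 to each side, more than the 0.0511 between the median and the highest of the 195. Base composition also stays open: CTCF, steroid receptor and AP-1 motifs had a median of 0.134 against 0.202 for AT-rich and 0.232 for GC-rich families, but they were picked for low values, with 27 of 46 among the lowest 195, and 1 family was taken out after its value was seen.

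Motifs whose known sites hold a CpG, a set chosen after the highest motifs were seen, had a median of 0.259 over 51 motifs against 0.182 for 729 other mouse-named motifs. A candidate explanation is that the score follows the CpG content of peaks. Among 11 bZIP names, most of them Fos and Jun dimers, listed in a version with and one without a CpG, the version with it was higher in 10. The test asked for all 11, and FOSL1::JUND went the other way by -0.0103. Only 1 pair differed by over 2 standard errors. The version with a CpG also lay in fewer peaks in all 11, and many names share a factor, so the pairs are not independent. The explanation by CpG content therefore stays open. GC content without CpG was tested with AP-2, ZIC and GLI motifs, GC-rich families taken to lack a CpG in their core. Their median was 0.207 against 0.206 for homeodomain motifs, only 0.00322 of the E2F excess, so they hardly exceeded homeodomain motifs. The rule was set after the values were seen, and the outcome depends on the AT-rich family used, since forkhead factors had 0.172. GC content without CpG therefore stays open. All GC-rich families together had 0.232 against 0.202 for AT-rich ones, where GC and CpG were not separated. Whether each of these sites lacks a CpG was not checked. Site types were assigned from general knowledge, not from the table.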
